A study of Homo sapiens with 20 samples.

How the data were processed

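Bulk RNA sequencing was available for 20 libraries of leukaemic blasts sorted from bone marrow taken at diagnosis, frozen and later thawed. The groups were AML, myeloid and T fractions of mixed phenotype acute leukaemia (MPAL), and myeloid and T fractions of AML with mixed phenotype (AML-MP), each with 4 libraries. Myeloid blasts were sorted as CD33 positive and CD7 negative, and T lymphoblasts as CD33 negative and CD7 positive; for AML the labels give no fraction. Libraries with the same diagnosis and number came from the same patient. A number shared between diagnoses has no meaning, so the main tests make no pairing across diagnoses. A library is named here by its group and patient number, for example MPAL myeloid 3. The myeloid and T libraries together are called the sorted libraries, as opposed to the AML libraries.

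The deposited table held raw read counts per gene symbol, without normalization. Per the submitters' processing notes, reads were trimmed with TrimGalore 0.6.4, aligned to hg19 with STAR 2.7.10b run with 2 passes, and counted with HTSeq 0.9.1. The labels name a total RNA kit with ribosomal depletion and a full-length cDNA kit for every sample, without saying which library was made with which. The gene annotation and the strand setting of the counting are not given in the sources used here. Reads over a gene that overlaps another on the opposite strand can therefore not be assigned with certainty; among the genes named in the text this holds for MEIS1, HOXA9, HOXB2, HOXB3, CEBPA, LEF1, DERL3, CFD, TCF7, SOCS2, NRIP1, LUC7L2, PRF1 and ISG15. Symbols were placed with GENCODE release 44 on GRCh37 (hg19). Of 45721 genes in the table, 25939 were matched by their symbol, 1079 by an older symbol, and 18703 were not matched. XIST, TSIX and Y-linked genes, 153 in all, were left out of all tests because the donors are people.

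Total counts per library ranged from 12010774 to 32016404. A gene with 0 counts in 1 library could be present at up to 3 counts, which was 0.0940 to 0.202 CPM (counts per 1e+06 counts). Where all 4 libraries of a group were at 0, folds are given as bounds against 3 counts summed over the group. Bounds cover counting error only. None of the 190 library pairs was a copy.

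Differential expression was tested with edgeR 4.0.16 in R 4.3.3, with the quasi-likelihood F test (robust), TMM scaling and filterByExpr, in a fit of all 20 libraries with 5 group means. This left 18493 genes, or 17362 in fits with the patient as a block. There were 7 contrasts. P-values were adjusted by Benjamini-Hochberg, and an adjusted p under 0.05 was taken as passing. Error of a log2 fold change is the standard error (SE) implied by the F statistic; other errors are SD. Levels are CPM with TMM scaling. Tested on simulated data with the spread of these libraries, the comparison of MPAL fractions recovered 34% of genes changed by a log2 fold of 2 and 70% of those changed by 4. The changed genes were taken only from those above a minimum mean count. Without a block the simulated libraries were independent, unlike the real pairs of a patient. With the patient as a block it recovered 80% and 92%, with 9 false calls among 16623 genes.

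Of 22 gene lists fixed together with the comparisons before the data were examined, those with at least 5 tested members were tested in each contrast with camera (limma 3.58.1, preset correlation 0.01), adjusted over the lists of a contrast. The lists cover T lineage, immature T, mature T and NK or cytotoxic genes, core myeloid, primary granule and monocytic genes, haematopoietic stem and progenitor genes, the LSC17 genes, HOX and MEIS1 genes, transcription factors of T-cell leukaemia, B lineage, plasma cell, plasmacytoid dendritic cell, erythroid and megakaryocyte genes, proliferation, MHC class II, interferon response, stress and immediate early genes, mitochondrially encoded genes and non-polyadenylated RNAs. Each was also tested with an estimated correlation and with fry, which tests whether the members of a list move, on balance, in 1 direction. A list score is the mean log2 CPM of its members in a library.

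The distance between the fractions of a patient was the root mean square log2 CPM difference over the 500 tested genes that differed most in that patient (prior count 2). The LSC17 score, a published stemness score, was the weighted sum of log2(CPM + 1) over the 14 of its 17 genes that are in the deposited table. Some weights are negative, so more RNA of those genes lowers the score. The LSC17 list ignores the weights. SMIM24, BEX3 and ADGRG1 are missing there under these and their older symbols, so the score is not on the published scale. Both were compared by exact two-sided permutation tests of 4 values against 4, which cannot give a p under 0.0286.

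Genes were chosen for naming by a fixed rule. It took, for each contrast, up to 6 higher and 6 lower genes with the largest fold among those that passed, with groups that did not overlap and a mean of at least 5 CPM. It added up to 4 members of each list that passed, with the smallest p, or the 2 with the smallest p for lineage and stem cell lists with none, and CD33, CD7, CD3E, MPO and CD34. Antigen receptor segments, pseudogenes, small RNAs, clone-named loci and genes that vary in the germline were left out of the first part.

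Alternatives were RLE scaling, DESeq2 1.42.0, limma voom with sample quality weights, no filter or a stricter filter (5 CPM in 4 libraries), a log2 fold threshold of 1, a block, only the groups compared, leaving out each library, other prior counts and pseudocounts, thinned counts and unweighted scores. The block was the patient within a diagnosis and in the interaction; between diagnoses, which share no patient, it was the shared number and has no biological meaning. Chosen after the data were seen were the estimated correlation within the fit with a block, leaving out each library for the lists, and 3 more: genes whose exons overlap no other gene, and the fits without AML-MP patient 1 and without MPAL patient 3. The exchange of fractions within patients, which keeps the pairs and has 8 distinct assignments, was also added then. Where an SD over 4 libraries is near 2 times its mean, 1 library holds nearly all of the signal. Numerical work outside R used numpy 2.4.6 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9.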

Results

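Leukaemic blasts from 4 patients with MPAL, 4 with AML-MP and 4 with AML were profiled by RNA sequencing. MPAL is an acute leukaemia whose blasts carry markers of more than 1 lineage, and AML-MP is AML with such a mixed phenotype. Each of the 8 patients with a mixed phenotype gave a myeloid and a T library, and each patient with AML gave 1 library. Total counts ranged from 12010774 in AML 4 to 32016404 in AML 1. Between 18271 and 23404 genes had at least 1 count in 19 of the libraries, and 39847 in AML-MP myeloid 1. Mitochondrial transcripts made up 2% to 20.9% of counts. The myeloid and T libraries of a patient resembled each other. In 8 of 8 patients the expression of the myeloid library, taken as deviation from its group, correlated across genes most closely with that patient's T library (0.564 to 0.797, against −0.42 to 0.0658 for other pairs of the same diagnosis; genes are not independent replicates).

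The first comparison asks how far the sorted fractions of MPAL differ in lineage programmes. In MPAL, T lymphoblasts had less RNA of primary granule genes, taken as a list, than myeloid blasts of the same patient. The primary granule list, enzymes and proteins stored in granules of myeloid precursors, was lower in the T library of 4 of 4 patients, with a mean T minus myeloid score of −2.54 ± 0.48 (SD, n = 4). RNASE3 (ENSG00000169397, chromosome 14, 21359544 to 21360507), an eosinophil granule protein, was at 1.74 ± 1.77 CPM in myeloid and 0.0527 ± 0.105 CPM in T libraries (n = 4 each). Its mean in T libraries was below the level that 3 counts give in 1 library. CFD (chromosome 19, 859453 to 867884), complement factor D, was at 51.6 ± 88.9 and 2.60 ± 2.78 CPM. The core myeloid list was also lower in 4 of 4 patients (−1.04 ± 1.07), as was the megakaryocyte list (−1.79 ± 1.67), and the T lineage list was higher in 4 of 4 (0.98 ± 0.99). Patients ranged from −2.61 to −0.316, from −4.28 to −0.734 and from 0.114 to 2.37. The largest difference was in MPAL patient 3 for core myeloid genes and in MPAL patient 4 for the other lists. The sort markers themselves differed unevenly. CD7 (chromosome 17, 80272744 to 80275484) was at 221 ± 105 CPM in myeloid and 634 ± 523 CPM in T libraries, higher in the T library of 4 of 4 patients. CD33 (chromosome 19, 51728320 to 51747115) was at 109 ± 112 and 114 ± 130 CPM, higher in T in 2 of 4. Within patients its T minus myeloid log2 difference averaged −0.505 ± 0.719 (SD), from −1.199 to 0.1667. MPO, the myeloid peroxidase and a member of the primary granule list, was at 1816 ± 1312 and 1353 ± 1417 CPM, higher in T in 1 of 4 patients. CD3E, a chain of the T-cell receptor complex, was at 17.6 ± 23.9 and 30.6 ± 25.1 CPM. CD34, a progenitor antigen, was at 1005 ± 801 and 909 ± 524 CPM.

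By camera, 9 lists passed in this contrast. Primary granule genes were lower in 9 of 10 tested members (median log2 fold change −3.52, camera adjusted p = 5.92e-13, adjusted p = 0.00684 with an estimated correlation), core myeloid genes in 13 of 15 (−0.68, 2.25e-09, adjusted p = 0.00684 with an estimated correlation) and megakaryocyte genes in 8 of 9 (−2.34, 1.04e-10, adjusted p = 0.0238 with an estimated correlation). With the patient as a block and an estimated correlation, these were adjusted p = 0.182, 0.182 and 0.184. With fry they were adjusted p = 0.277, 0.277 and 0.405. T lineage genes were higher in 22 of 22 (0.80, adjusted p = 0.000140, adjusted p = 0.302 with an estimated correlation). TCF7, a T-cell transcription factor, was at 42.1 ± 42.9 CPM in myeloid and 301 ± 443 CPM in T libraries. Monocytic genes were lower in 17 of 17 (−3.82, adjusted p = 3.81e-12, adjusted p = 0.126 with an estimated correlation), and the adjusted p was 0.676 without MPAL myeloid 3 alone but 0.00218 without both libraries of that patient. In that list MS4A6A was at 119 ± 209 CPM in myeloid and 7.40 ± 9.35 CPM in T libraries. MHC class II genes were lower in 8 of 8 (adjusted p = 3.47e-07, adjusted p = 0.249 with an estimated correlation) and stress genes in 13 of 14 (adjusted p = 2.38e-06, adjusted p = 0.272 with an estimated correlation). The latter had adjusted p = 0.0541 without MPAL myeloid 3. Without both libraries of MPAL patient 3 the MHC class II, stress, proliferation and plasmacytoid dendritic cell lists were at adjusted p = 0.166, 0.329, 0.166 and 0.854, and the other 5 lists passed. Proliferation genes were higher in 18 of 20 (adjusted p = 0.0106, adjusted p = 0.720 with an estimated correlation). This was adjusted p = 0.909, 0.981, 0.715 and 0.0794 without MPAL T 1, MPAL myeloid 2, MPAL T 3 and MPAL myeloid 4. Plasmacytoid dendritic cell genes were lower in 8 of 12 (adjusted p = 0.0176, adjusted p = 0.257 with an estimated correlation). This was adjusted p = 0.112, 0.175, 0.676 and 0.249 without MPAL T 1, MPAL myeloid 2, MPAL myeloid 3 and MPAL T 3, 0.760 among genes with no exonic overlap, and 0.164 with the patient as a block. With that block the HOX and MEIS1, B lineage and mitochondrially encoded lists passed as well, each at adjusted p = 0.0184, but not with an estimated correlation added (adjusted p = 0.405, 0.182 and 0.542). The immature T list did not pass (adjusted p = 0.467), with a median of 0.86 and a mean of −0.12. No single gene passed in edgeR (0 of 18493; 279 at an unadjusted p under 0.05; 0 in limma voom, 41 in DESeq2; with the patient as a block 0, and 930 unadjusted). Of no list did a member pass when adjusted over the list alone; with the patient as a block 6 primary granule genes, 5 monocytic genes and 1 megakaryocyte gene were lower, and 2 mature T genes higher. There were 87 genes (0.47%) whose fractions did not overlap. Chance gives 2.86% for independent libraries, but these are paired, and exchanging the fractions within patients gave 67 to 83 genes in the other 7 assignments.

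**Figure D1:**
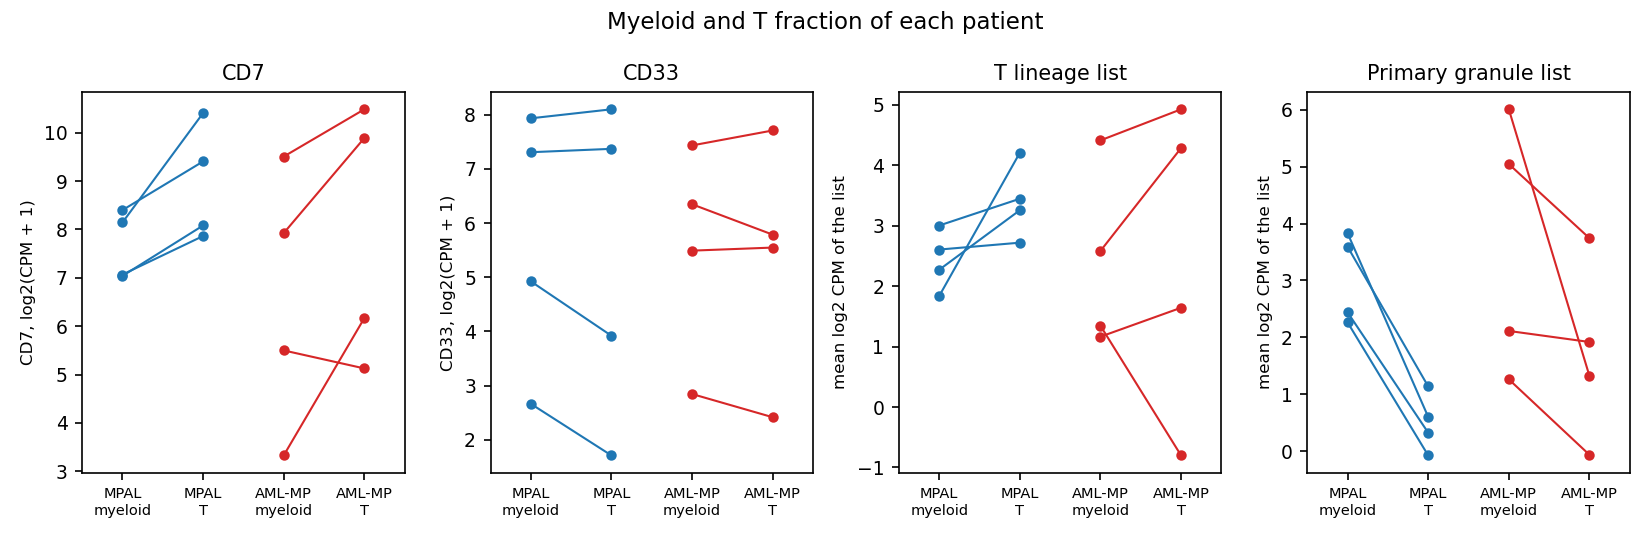
Levels in the myeloid and T library of each patient, with CD7 and CD33 as log2(CPM + 1) and the T lineage and primary granule lists as mean log2 CPM; lines join the libraries of a patient, blue for MPAL and red for AML-MP. The primary granule score is lower in the T library of 8 of 8 patients (4 of 4 in each diagnosis), while CD33 is lower in 4 of 8.

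The same question was put to AML-MP. Here too the T library had a lower primary granule score than the myeloid library in 4 of 4 patients (−1.88 ± 1.95, SD, n = 4), but patients ranged from −4.69 to −0.19. RNASE3 was at 13.3 ± 22.6 CPM in myeloid and 0.657 ± 0.840 CPM in T libraries, and RNASE2, a related granule ribonuclease, at 73.9 ± 132 and 5.17 ± 5.26 CPM. CD7 was at 256 ± 330 and 621 ± 686 CPM, higher in T in 3 of 4 patients. CD33 was at 75.6 ± 71.0 and 78.2 ± 89.6 CPM, higher in T in 2 of 4. Within patients its T minus myeloid log2 difference averaged −0.184 ± 0.417 (SD), from −0.5686 to 0.2777. MPO was at 1756 ± 2559 and 500.5 ± 695 CPM, CD3E at 13.19 ± 20.01 and 19.8 ± 21.4 CPM, and CD34 at 1993 ± 1064 and 2263 ± 1233 CPM. The T lineage score differed by 0.14 ± 1.63 and was higher in T in 3 of 4 patients, which ranged from −2.15 to 1.70. The exception was AML-MP patient 1, at 1.345 in the myeloid and −0.8013 in the T library. The myeloid library of that patient had 39847 genes detected.

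Of the lists, 4 passed camera in AML-MP, and none of these with an estimated correlation. Primary granule genes were lower in 10 of 10 members (median −2.46, camera adjusted p = 1.06e-06, adjusted p = 0.166 with an estimated correlation, adjusted p = 0.188 without AML-MP myeloid 3). Megakaryocyte genes were lower in 9 of 9 (adjusted p = 6.04e-06, adjusted p = 0.249 with an estimated correlation) and erythroid genes in 12 of 13 (adjusted p = 6.04e-06, adjusted p = 0.461 with an estimated correlation), at adjusted p = 0.702 and 0.248 without AML-MP myeloid 2. Interferon response genes were higher in 19 of 20, by a median of 0.22 (adjusted p = 0.00352, adjusted p = 0.697 with an estimated correlation). This was adjusted p = 0.138, 0.918, 0.881 and 0.0612 without AML-MP myeloid 1, T 2, myeloid 3 and T 4, and 0.1002 among genes with no exonic overlap. The patient as a block added the T lineage (adjusted p = 0.00184, 0.112 without it), monocytic (0.00184, 0.0979), core myeloid (0.0349, 0.164), mitochondrially encoded (0.0314, 0.112) and non-polyadenylated lists (0.0309, 0.166). None of these passed with an estimated correlation added to the block (adjusted p = 0.357 to 0.588). No gene passed in edgeR (0 of 18493; 173 at an unadjusted p under 0.05; 0 in limma voom, 8 in DESeq2; with the patient as a block 0, and 317 unadjusted), and no list had a member that passed when adjusted over the list alone. With the block 1 T lineage gene was higher, and 1 primary granule gene and 1 non-polyadenylated RNA lower. There were 74 genes (0.4%) with fractions that did not overlap, against 2.86% by chance for independent libraries and 44 to 96 genes in the other 7 assignments that exchange the fractions within patients.

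How far the fractions of a patient lay apart was compared between the diagnoses. The distance between fractions was 4.01 ± 0.80 in MPAL and 3.79 ± 0.87 in AML-MP (root mean square log2 difference, SD, n = 4 patients each), a difference of 0.225 that was smaller than the spread between patients (exact permutation p = 0.571, 0.371 to 1 over the alternatives). Leaving out each patient gave differences from −0.0560 to 0.535, the last without AML-MP patient 1, whose myeloid library had 39847 genes detected. Whether the T against myeloid difference of a gene differed between diagnoses was tested as an interaction. No gene passed in edgeR (0 of 18493; 155 at an unadjusted p under 0.05; 0 in limma voom, 21 in DESeq2; with the patient as a block 0, and 418 unadjusted). For 347 genes (1.88%, against 2.86% by chance) the patients' differences did not overlap between diagnoses. At the level of lists, monocytic genes were less reduced in the T fraction of AML-MP than of MPAL (17 of 17 members, camera adjusted p = 2.75e-07, adjusted p = 0.477 with an estimated correlation). This rested on MPAL patient 3, since the camera adjusted p was 0.276 without both libraries of that patient. Without MPAL myeloid 3 alone, which breaks the pair, it was 0.337 in the opposite direction. Core myeloid genes went the same way in 11 of 15 (adjusted p = 0.000445, adjusted p = 0.271 with an estimated correlation, adjusted p = 0.117 without MPAL myeloid 3 and 0.0612 without AML-MP myeloid 1), as did stress genes in 13 of 14 (adjusted p = 0.000445, adjusted p = 0.477 with an estimated correlation, adjusted p = 0.143 without MPAL myeloid 3 and 0.0962 without AML-MP T 1). Erythroid genes went the opposite way in 10 of 13 (adjusted p = 0.000445, adjusted p = 0.477 with an estimated correlation, adjusted p = 0.0653, 0.123, 0.0994 and 0.163 without MPAL T 1, MPAL myeloid 2, MPAL myeloid 3 and AML-MP myeloid 2).

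Other lists passed in the interaction with a larger p, and each lost its call in several of the 16 fits that left out 1 library. MHC class II genes were higher in the interaction in 8 of 8 members (camera adjusted p = 0.00384; 0.117 to 0.424 in the 6 fits without it), interferon response genes in 19 of 20 (0.00802; 0.0563 to 0.541 in 7 fits) and primary granule genes in 7 of 10 (0.0117; 0.0537 to 0.340 in 6 fits). Plasmacytoid dendritic cell genes were higher in 10 of 12 (0.0301; 0.0535 to 0.877 in 10 fits) and mitochondrially encoded genes in 13 of 13 (0.0349; 0.0652 to 0.996 in 10 fits). Proliferation genes were lower in 19 of 20 (0.00879; 0.0528 to 0.978 in 8 fits) and HOX and MEIS1 genes in 11 of 13 (0.0230; 0.0658 to 0.376 in 8 fits). Megakaryocyte genes passed as higher (0.0303; 0.0615 to 0.920 in 9 fits) with a median of −0.07 and a mean of 0.50, higher in 4 of 9. None of these passed with an estimated correlation (adjusted p = 0.477 for 6 of them, 0.593 for proliferation and 0.629 for mitochondrially encoded genes). With the patient as a block the immature T (adjusted p = 0.00492), T lineage (0.0224) and mature T lists (0.0292) passed as well, and the plasmacytoid dendritic cell (0.427) and megakaryocyte lists (0.0610) did not. The 3 gained lists did not pass with an estimated correlation added to the block (adjusted p = 0.412 to 0.532). Without both libraries of MPAL patient 3 the core myeloid (adjusted p = 0.311), stress (0.474), MHC class II (0.684), proliferation (0.133) and plasmacytoid dendritic cell lists (0.754) lost their calls. Without both libraries of AML-MP patient 1 the MHC class II (0.102), primary granule (0.323), megakaryocyte (0.166) and mitochondrially encoded lists (0.761) did. Among genes with no exonic overlap the interferon response and primary granule (adjusted p = 0.0678 each), plasmacytoid dendritic cell (0.655) and mitochondrially encoded lists (0.0790) lost their calls, and the MHC class II, HOX and MEIS1, and megakaryocyte lists had too few members to test. In the fit of group means the mature T, B lineage and T-cell leukaemia factor lists passed in none of the 7 contrasts (adjusted p from 0.0550, 0.0731 and 0.112).

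**Figure D2:**
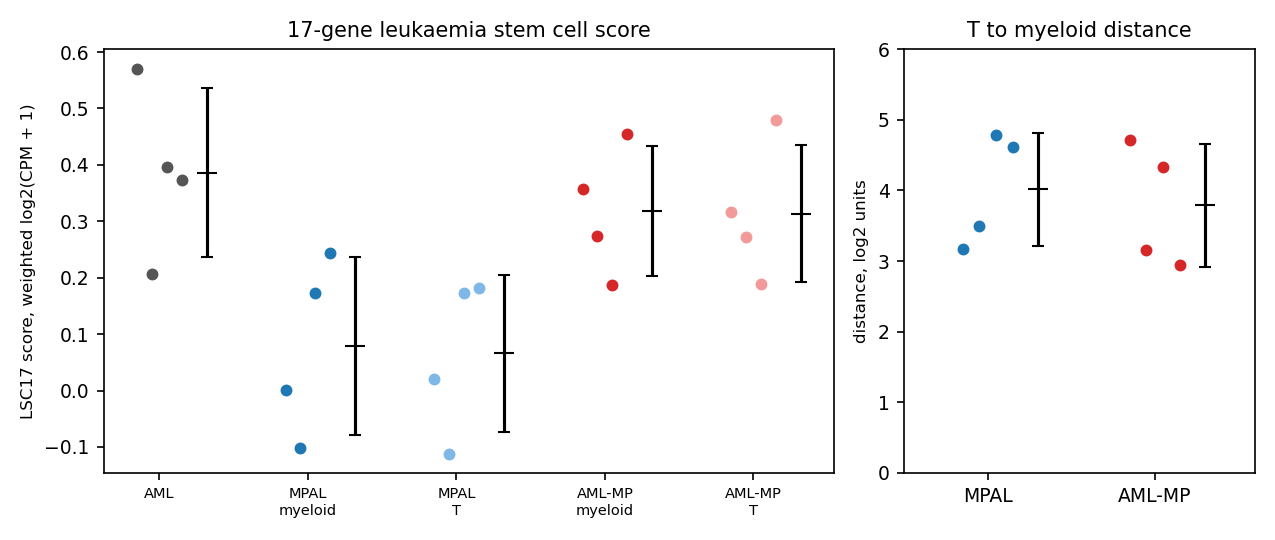
LSC17 score of each library by group, and distance between the T and myeloid library of each patient as root mean square log2 difference; points are libraries or patients. The LSC17 score averages 0.387 in AML, 0.0789 in MPAL myeloid and 0.318 in AML-MP myeloid libraries, and the distances average 4.01 in MPAL and 3.79 in AML-MP.

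Between the mixed phenotype diagnoses, the comparison concerns stem cell features. T lymphoblasts of AML-MP had more RNA of HOPX than those of MPAL. HOPX (ENSG00000171476, chromosome 4, 57514155 to 57548043), a homeodomain protein of stem and progenitor cells, rose from 11.9 ± 6.83 CPM in MPAL T to 328 ± 225 CPM in AML-MP T libraries (log2 fold change 4.78 ± 0.73 SE, n = 4 each, edgeR adjusted p = 0.0386). CYYR1 (chromosome 21, 27838528 to 27945605), a membrane protein gene, had 0 counts in the 4 MPAL T libraries and 28.0 ± 35.7 CPM in AML-MP T, at least 756-fold higher (adjusted p = 0.0386). HOX and MEIS1 genes, which specify position in the embryo and are expressed in haematopoietic progenitors, were higher in 13 of 13 members (median 1.89, camera adjusted p = 8.83e-06, adjusted p = 0.213 with an estimated correlation). No member passed over all genes and 3 did adjusted over the list alone. MEIS1 (chromosome 2, 66660584 to 66801001) was at 0.0601 ± 0.0853 CPM in MPAL T and 86.4 ± 101 CPM in AML-MP T libraries, and HOXB2 at 0 and 18.7 ± 22.2 CPM. Stem and progenitor genes were higher in 19 of 24 (2.21, adjusted p = 2.03e-05, adjusted p = 0.285 with an estimated correlation), with HOPX passing over all genes and 4 members adjusted over the list alone. The scores of both lists overlapped between diagnoses. AML-MP T 2 had a stem and progenitor score of 3.228, where MPAL T libraries were at 2.242 to 3.715 and other AML-MP T libraries at 3.925 to 6.106. Its HOX and MEIS1 score was 0.5777, against −2.61 to 0.6613 and 1.01 to 4.068. Interferon response genes were higher in 20 of 20 (1.48, adjusted p = 4.35e-07, adjusted p = 0.213 with an estimated correlation), with 0 members passing over all genes and 4 adjusted over the list alone. LSC17 genes were higher in 12 of 14 (adjusted p = 0.00175, adjusted p = 0.213 with an estimated correlation). Among them was SOCS2, a suppressor of cytokine signalling, at 21.1 ± 10.4 and 139 ± 96.5 CPM. Megakaryocyte genes were higher in 7 of 9 (adjusted p = 0.00313, adjusted p = 0.432 with an estimated correlation). Stress genes were higher in 13 of 14 (adjusted p = 0.0186, adjusted p = 0.690 with an estimated correlation). This was adjusted p = 0.0710, 0.0761, 0.0834 and 0.211 without MPAL T 1, 3 and 4 and AML-MP T 1, 0.258 and 0.0594 without AML-MP patient 1 and MPAL patient 3, and 0.0632 among genes with no exonic overlap.

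The markers CD7, CD33, CD3E and MPO did not pass between these T fractions, at edgeR adjusted p = 0.997, 0.910, 0.8995 and 0.789, nor did CD34 (log2 fold change 1.32 ± 0.58 SE, adjusted p = 0.382). CD2, a T-cell adhesion molecule, was at 46.2 ± 50.4 CPM in MPAL T and 0.620 ± 0.700 CPM in AML-MP T libraries (adjusted p = 0.241). In edgeR 2 of 18493 genes passed, HOPX and CYYR1. There were 2183 at an unadjusted p under 0.05, 19 in limma voom and 521 in DESeq2; 901 genes (4.87%, against 2.86% by chance) had groups that did not overlap. The count was 0 without any 1 of MPAL T 1, 2, 3 and 4 and AML-MP T 3 and 4, 1 without AML-MP T 1 and 4 without AML-MP T 2, and 1 without both libraries of AML-MP patient 1. For HOPX the adjusted p in the runs that lost the call was 0.0610 to 0.169, and for CYYR1 0.0610 to 0.169.

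The myeloid fractions of AML-MP and MPAL were compared for the same stem cell features. HOPX was at 319 ± 202 CPM in AML-MP myeloid and 15.6 ± 7.69 CPM in MPAL myeloid libraries, with groups that did not overlap, but missed the threshold (log2 fold change 4.35 ± 0.71 SE, edgeR adjusted p = 0.0800, adjusted p = 0.0190 without AML-MP myeloid 2). HOX and MEIS1 genes were higher in AML-MP in 13 of 13 members (median 2.66, camera adjusted p = 1.80e-08, adjusted p = 0.146 with an estimated correlation), with 0 passing over all genes and 6 adjusted over the list alone. With fry this list had adjusted p = 0.0191. MEIS1 was at 90.7 ± 110 CPM in AML-MP and 0.123 ± 0.247 CPM in MPAL myeloid libraries, and HOXA9 (chromosome 7, 27202057 to 27214799) at 68.2 ± 19.7 and 28.3 ± 39.0 CPM. Stem and progenitor genes were higher in 20 of 24 (1.93, adjusted p = 0.000424, adjusted p = 0.603 with an estimated correlation), with 0 members passing over all genes and 3 adjusted over the list alone. The score of this list was 3.346 in AML-MP myeloid 2, within the 2.381 to 3.999 of MPAL myeloid libraries. Other AML-MP myeloid libraries were at 4.341 to 6.334. Interferon response genes were higher in 19 of 20 (1.15, adjusted p = 0.00140, adjusted p = 0.703 with an estimated correlation). LSC17 genes were higher in 11 of 14 (adjusted p = 0.00453, adjusted p = 0.417 with an estimated correlation, adjusted p = 0.0818 without AML-MP myeloid 4). Proliferation genes were higher in 19 of 20 (adjusted p = 0.0234, adjusted p = 0.777 with an estimated correlation). It was adjusted p from 0.0589 to 0.298 without MPAL myeloid 2 or 4 or AML-MP myeloid 2, 3 or 4, and 0.0887 among genes with no exonic overlap. Monocytic genes were lower in 15 of 17 (adjusted p = 0.0132, adjusted p = 0.777 with an estimated correlation), but the adjusted p was 0.704 in the opposite direction without MPAL myeloid 3 and 0.0606 without AML-MP myeloid 1. In edgeR 0 of 18493 genes passed (2260 at an unadjusted p under 0.05; 1 in limma voom, 408 in DESeq2), and 2 without AML-MP myeloid 2; 1066 genes (5.76%, against 2.86% by chance) had groups that did not overlap. AML-MP myeloid 1, with 39847 genes detected, is 1 of the libraries compared; without both libraries of that patient 1 gene passed.

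**Figure D3:**
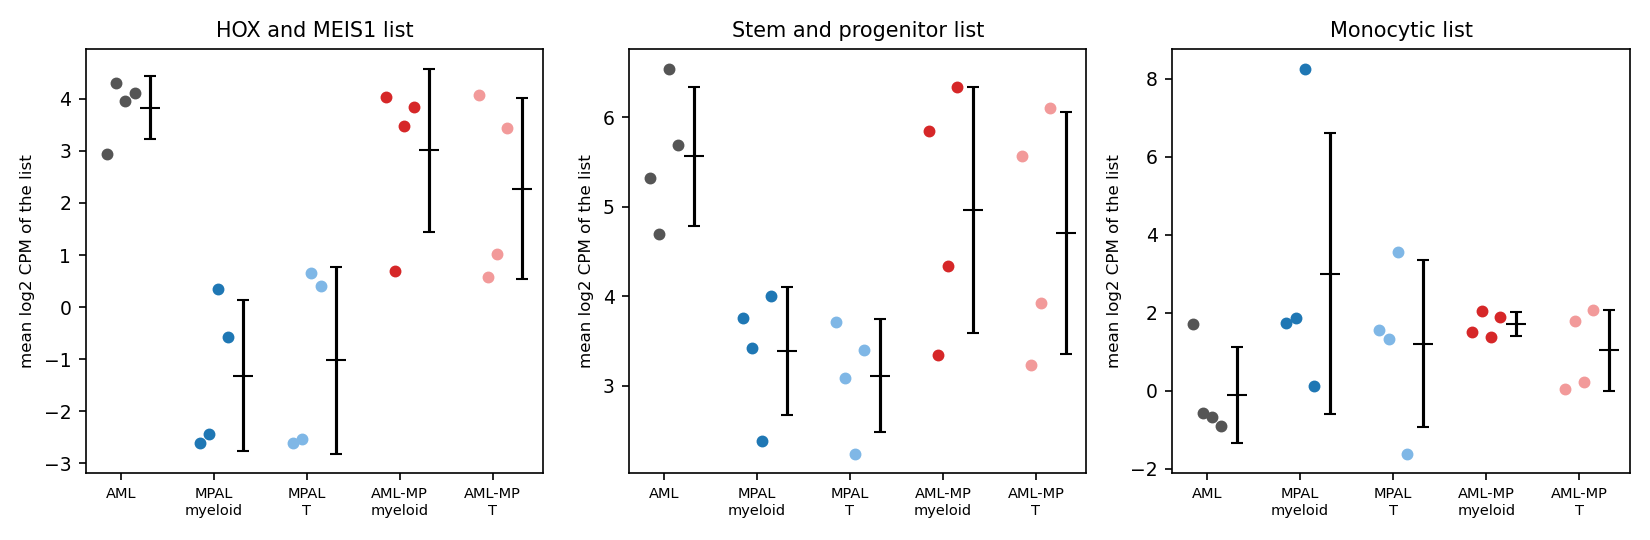
Scores of the HOX and MEIS1, stem and progenitor, and monocytic lists (mean log2 CPM) in each library by group; points are libraries, bars the mean and SD. The HOX and MEIS1 score averages 3.83 in AML, −1.32 and −1.02 in MPAL myeloid and T, and 3.02 and 2.27 in AML-MP myeloid and T libraries.

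The LSC17 score, here over 14 of its 17 genes, addressed stemness in a single value. It was 0.387 ± 0.149 in AML, 0.318 ± 0.115 in AML-MP myeloid, 0.314 ± 0.122 in AML-MP T, 0.0789 ± 0.158 in MPAL myeloid and 0.0658 ± 0.140 in MPAL T libraries (SD, n = 4 each). AML-MP myeloid blasts differed from AML by −0.0683, less than the spread between patients (exact permutation p = 0.514). MPAL myeloid blasts differed from AML by −0.308 (exact permutation p = 0.0571) and AML-MP from MPAL myeloid blasts by 0.239 (exact permutation p = 0.0571), both missing the threshold. With the unweighted mean of the 14 genes found both passed at exact permutation p = 0.0286, the smallest this design can give. That mean counts genes with negative weights as raising the score, so it does not measure stemness as the score does. Over all alternatives the exact permutation p was 0.0286 to 0.114 and 0.0286 to 0.143, and at least 0.0571 in both where the weights were kept. Among the score's genes, KIAA0125 (a long non-coding RNA, chromosome 14, 106345834 to 106398502) was at 733 ± 297 CPM in AML, 235 ± 66.5 CPM in AML-MP myeloid and 103 ± 58.2 CPM in MPAL myeloid libraries.

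The comparison of MPAL myeloid blasts with AML asks which myeloid programme they share. MPAL myeloid libraries had less RNA of stem cell and HOX genes than AML libraries. Disease cannot be told apart here from a difference in preparation or counting, and the AML fraction is not given. Among genes with no exonic overlap the stem and progenitor list passed (camera adjusted p = 8.76e-05). The HOX and MEIS1 list had too few such members to test. HOPX fell from 308 ± 151 CPM in AML to 15.6 ± 7.69 CPM (log2 fold change −4.30 ± 0.71 SE, n = 4 each, edgeR adjusted p = 0.00113), and KIAA0125 fell from 733 ± 297 to 103 ± 58.2 CPM (−2.83 ± 0.47 SE, adjusted p = 0.00113). Stem and progenitor genes were lower in 24 of 24 members (median −2.19, camera adjusted p = 1.90e-06, adjusted p = 0.113 with an estimated correlation), with 3 passing over all genes and 8 adjusted over the list alone. HOX and MEIS1 genes were lower in 13 of 13 (−3.08, adjusted p = 5.69e-07, adjusted p = 0.113 with an estimated correlation), with 3 and 6. MEIS1, a cofactor of HOX proteins, fell from 176 ± 111 to 0.123 ± 0.247 CPM (−10.45 ± 2.39 SE, adjusted p = 0.0178), though the adjusted p was 0.0599 to 0.0699 without MPAL myeloid 1, 3 or 4. HOXB3 (chromosome 17, 46626232 to 46682274) was at 17.3 ± 10.9 CPM in AML and 0 counts in MPAL, at least 492-fold lower (adjusted p = 0.0220, up to 0.0629 without any 1 MPAL library). NRIP1, a nuclear receptor corepressor, fell from 839 ± 498 to 111 ± 37.4 CPM (−2.92 ± 0.65 SE, adjusted p = 0.0145, up to 0.0675 without MPAL myeloid 1 or 4). LSC17 genes were lower in 12 of 14 (adjusted p = 0.000783, adjusted p = 0.113 with an estimated correlation), with 1 passing over all genes and 5 adjusted over the list alone. With fry the adjusted p was 0.00957 for the stem and progenitor and LSC17 lists, and 0.00449 for the HOX and MEIS1 list.

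The T lineage, immature T, NK or cytotoxic, and monocytic lists were higher in MPAL myeloid blasts than in AML by camera. Of the 35 splits of these libraries into groups of 4, a test chosen later, 3 to 20 gave these lists as small a p, which does not exclude chance. T lineage genes were higher in 17 of 22 members (median 3.01, or 2.53 with genes at 0 set to their bound; camera adjusted p = 0.000294, adjusted p = 0.321 with an estimated correlation), with 1 passing over all genes and 6 adjusted over the list alone. That gene was BCL11B (chromosome 14, 99635624 to 99738534), a transcription factor of T-cell commitment, at 0 counts in AML and 17.7 ± 19.2 CPM in MPAL, at least 547-fold higher (edgeR adjusted p = 0.0392, up to 0.1001 without MPAL myeloid 1 or 2 or any 1 AML library). NK or cytotoxic genes were higher in 15 of 15 (3.61, adjusted p = 0.000309, adjusted p = 0.113 with an estimated correlation), with 1 passing over all genes and adjusted over the list alone. Immature T genes were higher in 12 of 14 (adjusted p = 0.0300, adjusted p = 0.402 with an estimated correlation, adjusted p = 0.0889, 0.0564 and 0.0656 without MPAL myeloid 3, MPAL myeloid 4 and AML 4, and 0.0996 without MPAL patient 3). Monocytic genes were higher in 15 of 17 (6.20, adjusted p = 0.000294, adjusted p = 0.403 with an estimated correlation), with 3 passing over all genes and 13 adjusted over the list alone. The monocytic score was 8.262 in MPAL myeloid 3, 0.1221 to 1.869 in the other 3 MPAL myeloid libraries and −0.8982 to 1.721 in AML. Without MPAL myeloid 3 the list had adjusted p = 0.0138. The 3 genes lost their calls: S100A8, S100A9 and SERPINA1 passed at adjusted p = 0.0434, 0.0373 and 0.0245, and were at 0.390, 0.417 and 0.159 without MPAL myeloid 3, and over 0.05 without any 1 of the 4 AML libraries as well. S100A8 was at 0.143 ± 0.0913 CPM in AML and 499 ± 995 CPM in MPAL myeloid libraries. Primary granule genes were higher in 10 of 10 (adjusted p = 0.00628, adjusted p = 0.321 with an estimated correlation). MPO was at 127 ± 228 CPM in AML and 1816 ± 1312 CPM in MPAL (edgeR adjusted p = 0.315). CEBPA, a myeloid transcription factor, was at 53.2 ± 33.0 and 1.68 ± 1.76 CPM (adjusted p = 0.0792). For every gene and list compared with AML, disease cannot be told apart from preparation or counting. CEBPA, and DERL3 below, also overlap a gene on the opposite strand, as do MEIS1, HOXB3 and NRIP1. DERL3 (chromosome 22, 24176690 to 24181315), an endoplasmic reticulum protein of secretory cells, rose from 1.04 ± 0.480 to 20.2 ± 12.2 CPM (4.27 ± 0.67 SE, adjusted p = 0.000622) and was the member of the plasma cell list that passed. That list was higher in 5 of 6 (adjusted p = 0.0300, adjusted p = 0.113 with an estimated correlation, adjusted p = 0.0893, 0.0507 and 0.0552 without MPAL myeloid 2, AML 1 and AML 4). Proliferation genes were higher in 18 of 20 (adjusted p = 0.000315, adjusted p = 0.421 with an estimated correlation).

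Some differences between MPAL myeloid libraries and AML lay in RNA classes and in overlapping genes. The non-polyadenylated list includes replication-dependent histone genes, and its rise was not separated from that of proliferation genes. Non-polyadenylated RNAs were higher in MPAL myeloid libraries in 16 of 17 members (median 1.44, camera adjusted p = 6.00e-07, adjusted p = 0.113 with an estimated correlation). RN7SL1, the RNA of the signal recognition particle, was at 1.63 ± 1.82 CPM in AML and 30.3 ± 14.5 CPM in MPAL. Mitochondrially encoded genes were higher in 11 of 13 (adjusted p = 0.00123, adjusted p = 0.421 with an estimated correlation, adjusted p = 0.0567 without AML 3). A set of 8 genes had 0 counts in the 4 AML libraries and at least 50 counts in each of the 16 sorted libraries, and another 8 the reverse. PTPRCAP (chromosome 11, 67202981 to 67205153), a CD45-associated protein, was at 0 counts in AML and 311 ± 185 CPM in MPAL myeloid libraries, at least 9.62e+03-fold higher. LUC7L2 (chromosome 7, 139025105 to 139108203) was at 42.9 ± 14.4 CPM in AML and 0 counts in every sorted library. The transcript read through from the gene before it, C7orf55-LUC7L2, was at 0 in AML and 74.5 ± 40.2 CPM in MPAL myeloid libraries. In edgeR 585 of 18493 genes passed, 366 higher and 219 lower. There were 3011 at an unadjusted p under 0.05, and 2168 genes (11.7%, against 2.86% by chance) had groups that did not overlap. The count was 380 without AML 3, 502 without both libraries of MPAL patient 3, and 104 of 7255 among genes whose exons overlap no other gene. Of the 29 named genes that passed, 13 passed with each library left out in turn.

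The last comparison asks how AML-MP myeloid blasts relate to AML. Here too, disease cannot be told apart from preparation or counting. Proliferation genes were higher in AML-MP myeloid blasts in 20 of 20 members (median 1.99, camera adjusted p = 3.88e-06, adjusted p = 0.516 with an estimated correlation), with 4 passing over all genes and 10 adjusted over the list alone. TOP2A (chromosome 17, 38544777 to 38574148), a topoisomerase of dividing cells, rose from 3.14 ± 2.57 to 36.6 ± 18.1 CPM (log2 fold change 3.54 ± 0.88 SE, n = 4 each, edgeR adjusted p = 0.0186, up to 0.0609 without AML 2, 3 or 4). RRM2 (chromosome 2, 10260825 to 10351851), a ribonucleotide reductase subunit, rose from 1.80 ± 1.79 to 46.5 ± 32.6 CPM (4.69 ± 1.18 SE, adjusted p = 0.0197, up to 0.0593 without AML-MP myeloid 3 or AML 2 or 3). Interferon response genes were higher in 18 of 20 (0.97, adjusted p = 0.00681, adjusted p = 0.572 with an estimated correlation, adjusted p = 0.117 among genes with no exonic overlap), with 1 passing over all genes and 3 adjusted over the list alone. IFI6, an interferon-induced protein, rose from 36.0 ± 7.46 to 172 ± 136 CPM (adjusted p = 0.0251, up to 0.118 without AML-MP myeloid 2 or 3 or AML 1, 3 or 4). HOX and MEIS1 genes did not pass as a list (adjusted p = 0.532), nor did the stem and progenitor genes (0.137) or LSC17 genes (0.450). HOPX was at 319 ± 202 CPM in AML-MP and 308 ± 151 CPM in AML, and HOXA9 at 68.2 ± 19.7 and 65.6 ± 21.5 CPM.

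The T lineage, NK or cytotoxic, primary granule and monocytic lists were higher in AML-MP myeloid blasts than in AML by camera. Of the 35 splits of these libraries into groups of 4, 6 to 16 gave these lists as small a p, which does not exclude chance. CCL5 (chromosome 17, 34198495 to 34207797), a chemokine of T and NK cells, rose from 1.91 ± 1.27 to 21.6 ± 14.0 CPM (log2 fold change 3.496 ± 0.78 SE, edgeR adjusted p = 0.0101) and DERL3 from 1.04 ± 0.480 to 14.6 ± 11.1 CPM (3.80 ± 0.65 SE, adjusted p = 0.00131). T lineage genes were higher in 16 of 22 (2.12, camera adjusted p = 0.00751, adjusted p = 0.597 with an estimated correlation, adjusted p = 0.0567 without AML-MP myeloid 2), with 2 passing over all genes and 5 adjusted over the list alone. LEF1, a transcription factor of T-cell development, rose from 0.0924 ± 0.0938 to 135 ± 201 CPM (10.48 ± 2.89 SE, adjusted p = 0.0330, up to 0.0989 without AML-MP myeloid 2 or 3 or any 1 AML library). NK or cytotoxic genes were higher in 15 of 15 (median 3.24, or 3.10 with genes at 0 set to their bound, adjusted p = 0.00663, adjusted p = 0.516 with an estimated correlation), with 0 members passing over all genes or over the list alone. Primary granule genes were higher in 10 of 10 (adjusted p = 0.0123, adjusted p = 0.516 with an estimated correlation, adjusted p = 0.0575 without AML-MP myeloid 3), with 0 and 2. Monocytic genes were higher in 12 of 17 (adjusted p = 0.0238, adjusted p = 0.762 with an estimated correlation), with 0 and 0. Lower in AML-MP was SMIM3, a small membrane protein gene, at 139 ± 86.8 CPM in AML and 0.224 ± 0.264 CPM (−9.24 ± 1.52 SE, adjusted p = 0.000875). CEBPA (chromosome 19, 33790840 to 33793440) fell from 53.2 ± 33.0 to 1.47 ± 0.684 CPM (−5.17 ± 1.51 SE, adjusted p = 0.0440, up to 0.126 without any 1 of the 8 libraries). As in MPAL myeloid libraries, disease cannot be told apart from preparation or counting for any gene or list here. LEF1, CEBPA and DERL3 also overlap a gene on the opposite strand. EMP1, an epithelial membrane protein of the LSC17 set, fell from 204 ± 205 to 15.7 ± 12.6 CPM (−3.70 ± 0.98 SE, adjusted p = 0.0274, up to 0.113 without AML-MP myeloid 2, 3 or 4 or AML 1 or 3).

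RNA classes and overlapping genes differed between AML-MP myeloid libraries and AML as well. Non-polyadenylated RNAs were higher in AML-MP myeloid libraries in 14 of 17 members (median 0.79, camera adjusted p = 0.00476, adjusted p = 0.516 with an estimated correlation). HIST1H4C, a replication-dependent histone gene, rose from 27.6 ± 16.9 to 222 ± 85.8 CPM (log2 fold change 3.00 ± 0.52 SE, edgeR adjusted p = 0.00145). Proliferation genes were also higher, and the rise of histone genes was not separated from theirs. Mitochondrially encoded genes were higher in 10 of 13 (adjusted p = 0.0251, adjusted p = 0.762 with an estimated correlation, adjusted p = 0.0838, 0.151 and 0.349 without AML-MP myeloid 1, AML-MP myeloid 3 and AML 3, and 0.181 among genes with no exonic overlap). PTPRCAP was at 0 counts in AML and 342 ± 124 CPM in AML-MP myeloid libraries, at least 1.05e+04-fold higher. Fold changes correlated with exonic length across 14844 genes (Spearman −0.182; genes are not independent replicates). In edgeR 1288 of 18493 genes passed, 776 higher and 512 lower. There were 3737 at an unadjusted p under 0.05, and 2755 genes (14.9%, against 2.86% by chance) had groups that did not overlap. The count was 646, 756 and 768 without AML-MP myeloid 3, AML 3 and AML 4, 1646 without both libraries of AML-MP patient 1, and 402 of 7255 among genes whose exons overlap no other gene. Of the 34 named genes that passed, 14 passed with each library left out in turn.

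**Figure D4:**
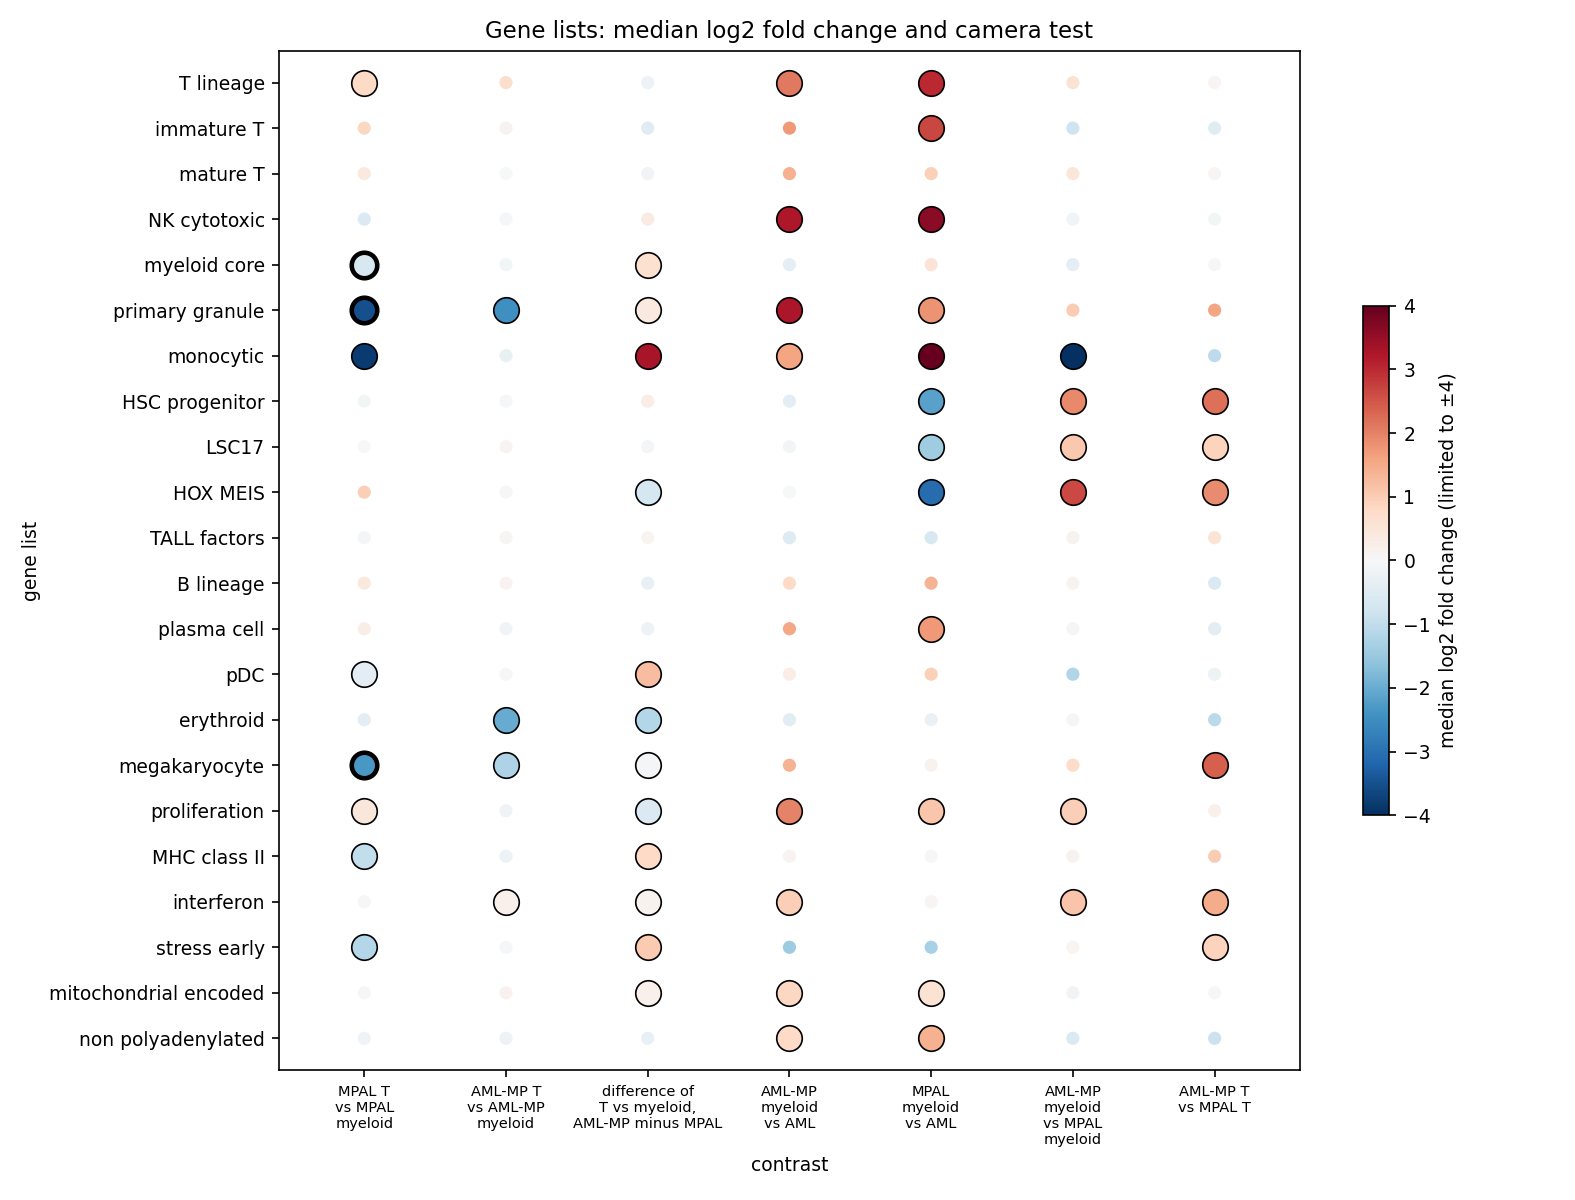
Results of 22 gene lists in the 7 contrasts; colour gives the median log2 fold change of a list, limited to −4 and 4, large outlined points have a camera adjusted p under 0.05 and a thick outline marks those that hold with an estimated correlation. The latter are the primary granule, core myeloid and megakaryocyte lists between the fractions of MPAL. These did not pass with fry (adjusted p = 0.277, 0.277 and 0.405).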

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

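Of the tests below only the removal of the length trend was predicted before it was run, and the other tests were chosen after the result was seen.

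The AML libraries differed from the sorted libraries in genes that were fully on in one set and at 0 in the other. Of genes at 0 in every AML library and at 50 counts or more in every sorted library, or the reverse, 10 of 10 placed on the genome (100%) share exons with a gene on the same strand, against 18.5% of other tested genes (Fisher exact p = 4.87e-08), which goes with another gene annotation in the counting. Among genes with no exonic overlap 6.35% still passed between AML-MP myeloid and AML, which argues against this as the whole cause. Among genes that overlap only on the same strand 12.3% passed. Between MPAL myeloid and AML these shares were 2.26% and 7.86%, so the calls there lean more on overlapping genes. With the trend with exonic length removed 766 genes passed, 737 of them among the 1182 that passed without this, which argues against a length bias as the whole cause. No split of the 8 libraries other than the real one called any gene, for the 1288 and for the 585 genes (1 of 35 splits with as many in both, highest other 0). This is the smallest share possible, and other splits put the difference between AML and sorted libraries into the spread. It is evidence against chance but does not exclude it. A difference in preparation or counting, which the labels do not settle, cannot be told apart from disease here.

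AML-MP myeloid 1 had 39847 genes detected, where the other 3 libraries of the group had 19181 to 20552. Thinned to the smallest library it still had 39088, which argues against depth. Of 4652 autosomal genes at 0 in the other 19 libraries, 63% were detected there, at up to 76 counts, and their counts rose with exonic length (Spearman 0.575 across genes, which are not independent replicates). This goes with reads from genomic DNA.

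The monocytic list passed for a difference between diagnoses in its T against myeloid change (camera adjusted p = 2.753e-07, adjusted p = 0.4767 with an estimated correlation; 5 of 35 splits gave as small a p). Without MPAL patient 3 the adjusted p was 0.276, which goes with 1 patient with high monocytic RNA in the myeloid fraction.

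Far samples were found in 15 of 157 groups tested, where chance gives about 1 in 20, or 7.8. Total counts reached 27254330 in 1 MPAL myeloid library (others 19332473 to 20668084). The immature T score was −1.308 in 1 AML-MP myeloid library (others 0.3153 to 0.616). The NK or cytotoxic score was 2.107 in 1 MPAL T library (others 0.3977 to 0.6764). The monocytic score was 1.721 in 1 AML library (others −0.8982 to −0.5611). The megakaryocyte score was 5.06 in 1 AML-MP myeloid library (others 1.29 to 1.869). The MHC class II score was 9.231 in 1 AML library (others 7.419 to 7.579). The interferon score was 4.753 in 1 MPAL myeloid library (others 3.824 to 3.929). The stress score was 5.58 in 1 MPAL T library (others 3.576 to 3.804) and 6.257 in 1 AML-MP T library (others 4.812 to 5.022). The non-polyadenylated score was 1.499 in 1 MPAL myeloid library (others 2.912 to 3.154). CD7 was at 122.4 CPM in 1 AML library (others 1.037 to 9.988), and MPO at 468.6 CPM in 1 (others 0.4724 to 27.42). CD3E was at 53.12 CPM in 1 MPAL myeloid library (others 2.159 to 10.08) and at 42.83 CPM in 1 AML-MP myeloid library (others 0.6797 to 7.731).

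Besides the monocytic list, 11 lists passed by camera for a difference between diagnoses in their T against myeloid change, and none of them with an estimated correlation (adjusted p = 0.271 to 0.629). Camera adjusted p was 0.0004449 for the core myeloid, erythroid and stress lists, 0.003836 for MHC class II, 0.008018 for interferon response and 0.008792 for proliferation. It was 0.01167 for primary granule, 0.02305 for HOX and MEIS1, 0.0301 for plasmacytoid dendritic cell, 0.03025 for megakaryocyte and 0.0349 for mitochondrially encoded genes. The real split called 12 lists and the highest other 11 (1 of 35 splits with as many), a margin of 1 list. List by list, from 2 of 35 splits (interferon response, HOX and MEIS1) to 16 (megakaryocyte) gave as small a p, so chance is excluded for none of the 11.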

How the results depend on the processing

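The alternatives for overlapping genes, AML-MP patient 1 and MPAL patient 3 are tests chosen after the result was seen, as were, for lists, each library left out and the block with an estimated correlation; the rest were planned. Counts of genes moved with the filter, the tool and single libraries, and the cause was not tested. For AML-MP myeloid against AML (1288) they were 750 with no filter, 1986 in limma voom, 2229 in DESeq2, 402 among the 7255 genes with no exonic overlap, and 646 to 1442 with each library left out. For MPAL myeloid against AML (585) they were 380, 1059, 1546, 104 and 380 to 477. For AML-MP against MPAL myeloid (0) they were 1 in limma voom, 408 in DESeq2, 9 with the shared number as a block, 2 with no exonic overlap, 1 without AML-MP patient 1, and 0 to 2 with each library left out. For AML-MP T against MPAL T (2) they were 0 with no filter, 7 with the stricter filter, 19 in limma voom, 521 in DESeq2, 24 with the shared number as a block and 0 with only the groups compared. They were 1 without AML-MP patient 1, 0 without MPAL patient 3, and 0 to 4 with each library left out. Diagnoses share no patient, so that block has no biological meaning. DESeq2 called 41 genes between the fractions of MPAL, 8 between those of AML-MP and 21 in the interaction, against 0 each. In simulated data it made 90 false calls where edgeR made 6. The simulated libraries were independent, unlike the real pairs of a patient, so these false calls are no yardstick for the real counts. The unweighted LSC17 mean differed by −1.95 between MPAL myeloid and AML and by 1.45 between AML-MP and MPAL myeloid. Of 154 list results, 54 were weaker with an estimated correlation, 49 weaker and 1 stronger with fry, and 154 the same with RLE scaling. Lists that kept their call with fry lay between diagnoses. Between MPAL myeloid and AML they were HOX and MEIS1 (fry adjusted p = 0.00449) and plasma cell (0.0126). Stem and progenitor, LSC17, NK or cytotoxic and non-polyadenylated lists did so there as well (0.00957 each). HOX and MEIS1 passed between AML-MP and MPAL myeloid (0.0191), and NK or cytotoxic between AML-MP myeloid and AML (0.0293). Among genes with no exonic overlap 10 were weaker, 3 stronger and 113 the same; the HOX and MEIS1, MHC class II, megakaryocyte and plasma cell lists had fewer than 5 members left and could not be tested.

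Some list results reversed. Between fractions and in the interaction, a fit without 1 library keeps the other library of that patient, so the pair is broken. The monocytic interaction ranged from adjusted p = 1.033e-11 to 0.3369, the latter reversed without MPAL myeloid 3. The monocytic list between AML-MP and MPAL myeloid ranged from 0.0002829 to 0.7039, reversed without that library, and was 0.7156, reversed, without MPAL patient 3. The proliferation list between the fractions of AML-MP ranged from 1.97e-06 to 0.9694 and reversed without AML-MP T 1 (0.01375). Its interaction ranged from 3.049e-08 to 0.9779, the latter reversed without AML-MP T 1. Without both libraries of AML-MP patient 1 the interaction was at 0.003843. Without MPAL patient 3 the plasmacytoid dendritic cell list reversed between the fractions of MPAL (0.8544; 0.9368 with the patient as a block) and in the interaction (0.7544; 0.6015 with the block).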

Other observations

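The split tests below, and the genes described, were chosen after the result was seen.

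Several lymphoid genes were present in the myeloid as well as the T fractions. CD3D, a chain of the T-cell receptor complex, was at 120.2 ± 63.1 CPM in MPAL myeloid and 157 ± 68.5 CPM in MPAL T libraries, and at 146 ± 140 and 216 ± 201 CPM in AML-MP, against 6.04 ± 8.26 CPM in AML (SD, n = 4 each). PRF1, the pore-forming protein of cytotoxic cells, was at 70.5 ± 46.1 and 88.7 ± 80.8 CPM in MPAL and 62.7 ± 55.6 and 82.0 ± 77.4 CPM in AML-MP, against 3.93 ± 5.10 CPM in AML. DNTT, the terminal transferase of early lymphocytes, was at 195 ± 163 and 412 ± 451 CPM in MPAL, 92.0 ± 180 and 438 ± 871 CPM in AML-MP and 2.49 ± 2.92 CPM in AML. The AML-MP means of DNTT rest on 1 patient, at 361.5 and 1745 CPM, where the other 3 were at 0.2621 to 5.056 and 0 to 7.639 CPM.

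LAPTM4B, a lysosomal protein of the LSC17 set, was at 313 ± 189 CPM in AML, 296 ± 366 CPM in AML-MP myeloid and 3.76 ± 4.06 CPM in MPAL myeloid libraries, and did not pass between the last 2 (edgeR adjusted p = 0.312). ISG15, a ubiquitin-like protein induced by interferon, was at 121 ± 88.7 CPM in AML-MP myeloid and 43.8 ± 31.5 CPM in MPAL myeloid libraries (adjusted p = 0.473). PF4, a platelet chemokine, was at 1.04 ± 0.622 CPM in MPAL myeloid and 0.132 ± 0.264 CPM in MPAL T libraries, and at 21.2 ± 36.1 and 1.95 ± 1.22 CPM in AML-MP, where 1 myeloid library was at 75.26 CPM and the others at 0.9063 to 7.145 CPM.

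Splits of the same libraries into other groups of 4 called no gene in the interaction (real 0, 35 of 35 splits with as many, highest other 0) or between AML-MP and MPAL myeloid (real 0, 35 of 35, highest other 0). Between AML-MP T and MPAL T the real split called 2 genes and the highest other 0 (1 of 35, the smallest share possible). This margin is 2 genes, and the count was 0 without any 1 of 6 of the 8 libraries, so it is weak evidence against chance. Between the fractions of MPAL the real split called 0 genes and the highest other 312, and between those of AML-MP 0 and 286 (35 of 35 splits with as many in both). Those splits keep libraries of the same patient together, and the 8 that part every pair called 0, which points to the structure of the samples by patient.

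Chance cannot be excluded for the number of lists called in the 6 contrasts other than the interaction, where the margin was 1 list. The real split called 9 lists between the fractions of MPAL (8 of 35 splits with as many, highest other 11) and 4 in AML-MP (29 of 35, highest other 13). It called 8 between AML-MP myeloid and AML (15 of 35, highest other 14) and 12 between MPAL myeloid and AML (8 of 35, highest other 13). It called 6 between AML-MP and MPAL myeloid (23 of 35, highest other 12) and 6 between their T fractions (20 of 35, highest other 13). List by list, the splits with a camera p as small as the real one were 1 of 35 for HOX and MEIS1 genes between MPAL myeloid and AML, the smallest share possible. For every other list called between diagnoses they were 2 to 32 of 35, which does not exclude chance. The monocytic list was at 20 between MPAL myeloid and AML, 8 between AML-MP myeloid and AML, and 32 between AML-MP and MPAL myeloid. The T lineage list was at 5 for MPAL myeloid and 16 for AML-MP myeloid, each against AML. Between fractions the splits that part every pair number 8, too few for a share under 0.05.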
